A study of Homo sapiens with 6 samples.

How the data were processed

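RNA abundance was measured in A549 cells with a whole-transcript array on which 1 transcript cluster (the set of probes for a transcribed locus) gives 1 value. A549 is an established human lung adenocarcinoma line. Per the labels, cells stably carrying a lentiviral control shRNA or a lentiviral shRNA against S100A4 were grown in medium with 10% serum to about 70% confluence, and total RNA was extracted with Trizol, amplified and biotin-labelled. The labels give 3 days of culture in the sample description and 2 days in the treatment protocol, and this difference could not be settled.

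The authors deposited a table of log2 signal per feature and array, and the program that summarised it is not given in the sources used here. That table holds 70523 features. Its scale was read from its values, whose ceiling is 19.93, and array medians over named genes lie between 5.48 and 5.52. The authors also deposited a workbook with a log2 mean per group, an unadjusted p-value and a linear ratio per transcript cluster, per the file headers. Partek 6.0 is named in the submitters' processing notes. The deposited ratio equals 2 to the power of the difference between the deposited group means. Levels in the workbook are not the means of the value table, since the levels of the same genes correlate across genes at only r = 0.78, so the workbook comes from another summarisation of the arrays. It has no values per array and was used for gene symbols, as an alternative, and where the authors' deposited table is named. A second sheet holds the same values for 26842 of the rows and was not used.

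Of the transcript clusters, 26831 carried a gene symbol and 40697 did not. The symbol column never holds more than 1 symbol, so clusters that cover several genes could not be told apart from the rest. Symbols were updated through the RefSeq table of assembly GRCh38.p14, used for names and neighbours only: 22675 clusters matched by accession, 2135 by current symbol and 976 by an older symbol, and 1044 kept the name in the file. A date stood in place of the symbol in 27 clusters, and 1 of these that no accession resolved was left out. For 668 genes with several clusters the cluster with the highest mean over the 6 arrays was kept, which left 25141 genes. Control probe sets were left out of the tests, and genes were not filtered on signal. No detection calls were used. The negative controls named here are the array's negative housekeeping control probe sets, whose median was between 4.18 and 4.27 on each array.

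Arrays were grouped by their labels as control shRNA or S100A4 shRNA, 3 each. The arrays are labelled as biological replicates, and the labels name 1 shRNA per group and no scan date or batch. No array pair was a duplicate, since at most 0.0278% of gene values were identical between any 2 arrays. The log2 values were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p under 0.05. SDs are over the 3 arrays of a group and standard errors (SE) are limma's. S100A4 was also tested with an exact permutation test of the 6 values, whose smallest p is 0.1. The replicate numbers shared by the groups were not treated as pairs.

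Before the data were examined, 26 gene lists were fixed, and 25 of them had at least 5 measured members and were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists. The list of mitochondrial DNA genes had 0 measured members, since the clusters of that genome carry no symbol. camera with an estimated correlation and fry were alternatives. Counts of called members "adjusted over the list alone" use Benjamini-Hochberg within the list.

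Genes are named by a rule that was also fixed in advance. S100A4 is always named. The 12 largest rises and 12 largest falls are named among called genes with no overlap between the groups and a mean in the higher group above the median of all genes, leaving out uncharacterised, antisense, small RNA and pseudogene symbols. Each list gives up to 4 called members with the smallest p, and a list with no called member gives up to 2 as values. Any other gene in the text was chosen after its values were seen. Some genes that the rule names are not reported here.

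Data were simulated for the comparison of S100A4 shRNA with control shRNA over 25141 genes, with the variance that eBayes gave each gene. There limma called 1 of 50 genes changed 1.2-fold, 46 of 50 changed 1.5-fold, 48 of 50 changed 2-fold and 50 of 50 changed 3-fold. It also called 10 unchanged genes and gave 0 wrong directions. camera called the shifted list and 0 unshifted lists. The changed genes were drawn from those above the median signal, and all genes were simulated independently. Only 50 genes were changed at each fold, far fewer than the 2910 called below, so the adjusted threshold was stricter than in the data. The shares called in the simulation therefore need not hold for the data. The simulated lists thus had no correlation between members, so this result does not cover lists with correlated members. Among the lists called below, the estimated correlation ran from 0.062 for matrix proteolysis to 0.47 for sterol and lipid synthesis.

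Alternatives fixed before the data were examined were quantile normalization, centring of each array on its median, removal of the lowest 25% or 50% of genes by mean signal, the mean of a gene's clusters, all transcript clusters as the tested set, eBayes with trend and robust, array weights, an ordinary linear model per gene, stricter thresholds, the replicate number as a block, each array left out in turn, and the other list tests. Cyclic loess, the authors' workbook means and p-values, and lists without shared members were added after the data were seen.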

Results

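Expression in A549 cells carrying an shRNA against S100A4 was compared with that in A549 cells carrying a control shRNA, with 3 arrays in each group. S100A4 is a small calcium-binding protein known for its association with metastasis. The series asks which molecules downstream of S100A4 alter mitochondrial metabolism and invasion of lung cancer cells. Values for 25141 genes are log2 signals, and the number of arrays limits the precision. Arrays of a group correlated across genes at r between 0.9966 and 0.9979, and arrays of different groups at r between 0.9926 and 0.9945. The p-values measure the spread between these samples, and with 1 shRNA per group they do not cover differences between shRNAs or between independently made lines.

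S100A4, the target, fell from 7.29 ± 0.24 on the control arrays to 5.56 ± 0.16 on the S100A4 shRNA arrays (log2 signal, SD, n = 3 each), a log2 fold of -1.73 (SE 0.13, 3.32-fold lower, limma adjusted p = 0.000453). Single arrays read 7.57, 7.12 and 7.18 with control shRNA and 5.74, 5.51 and 5.44 with S100A4 shRNA. Among falls of all genes by log2 fold, S100A4 ranked 10. The exact permutation test gave p = 0.1 (two-sided), the smallest that 3 against 3 arrays allow. In the authors' deposited table the ratio of S100A4 shRNA to control shRNA was 0.390 for S100A4.

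**Figure D1:**
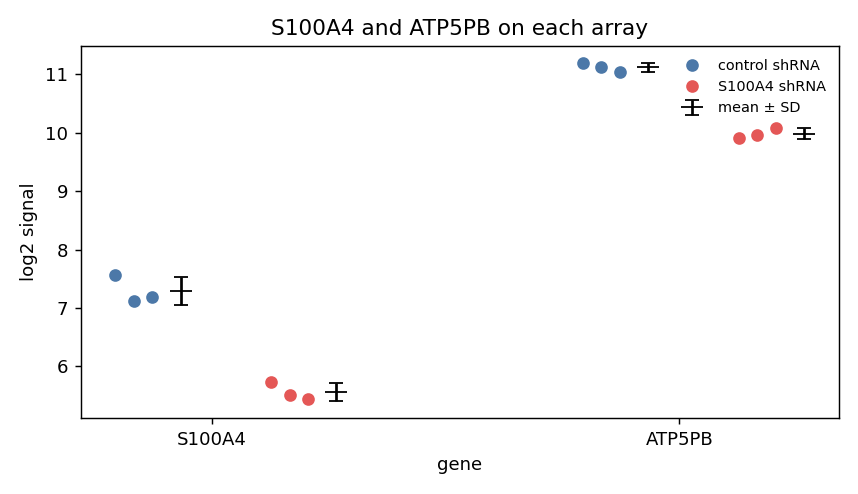
Log2 signal of S100A4 and ATP5PB on each of the 3 control shRNA and 3 S100A4 shRNA arrays (points), with the mean and SD of each group (black). For both genes each S100A4 shRNA array lies below each control array, with group means of 7.29 and 5.56 for S100A4 and 11.1 and 9.98 for ATP5PB.

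Across the 25141 genes, limma called 2910, of which 1529 were higher and 1381 lower with S100A4 shRNA. Of these, 760 changed at least 1.5-fold (468 higher, 292 lower) and 171 at least 2-fold (115 higher, 56 lower). The groups did not overlap for 32.8% of all genes, against 10% by chance. The largest rise was of FGA, the fibrinogen alpha chain, from 5.31 ± 0.10 to 8.15 ± 0.16 (SD, n = 3 each), a log2 fold of 2.84. FGB, the fibrinogen beta chain, rose by a log2 fold of 2.28. NT5E, the ectoenzyme that makes adenosine from AMP, rose by 2.69, and HAS2, a hyaluronan synthase, by 2.28. The collagen-binding integrin chain ITGA11 rose by 2.25 and the collagen prolyl hydroxylase subunit P4HA3 by 2.11. The other named rises were TM4SF20 (2.29), NAV1 (2.14), CDA (2.10), HGD (2.05) and RND1 (2.05). Their limma adjusted p-values ran from 1.8e-05 for HAS2 to 0.000457 for CDA.

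The largest fall was of GFRA1, a co-receptor for glial cell line-derived neurotrophic factor, from 9.54 ± 0.02 to 7.17 ± 0.11 (SD, n = 3 each), a log2 fold of -2.37. The nuclear receptor NR5A2 had a log2 fold of -2.34, the caveolar protein CAVIN2 of -2.09 and the kinase STK26 of -2.08. The proteoglycan versican, VCAN, had a log2 fold of -1.98 and the protease-activated receptor F2RL2 of -1.94. E2F4, a transcription factor of the cell cycle, had a log2 fold of -1.73. The remaining named falls were SLFN11 (-1.70), CDCA7L (-1.67) and COMMD7 (-1.64). Their limma adjusted p-values ran from 1.8e-05 for GFRA1 to 0.000524 for COMMD7. All of these genes moved the same way in the authors' deposited table, with smaller fold changes (ratios of 3.30 for FGA, 2.64 for NT5E and 0.427 for GFRA1). Leaving out 1 array at a time gave between 1539 and 2583 called genes, and the count fell by over 1.5 times without control replicate 2 (1816), control replicate 3 (1539), S100A4 shRNA replicate 1 (1801) or S100A4 shRNA replicate 3 (1767). The authors' p-values, adjusted over the same genes, gave 532 genes, 387 of them also called by limma here, and 60 of the other genes and list members named by rule lost their call there.

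**Figure D2:**
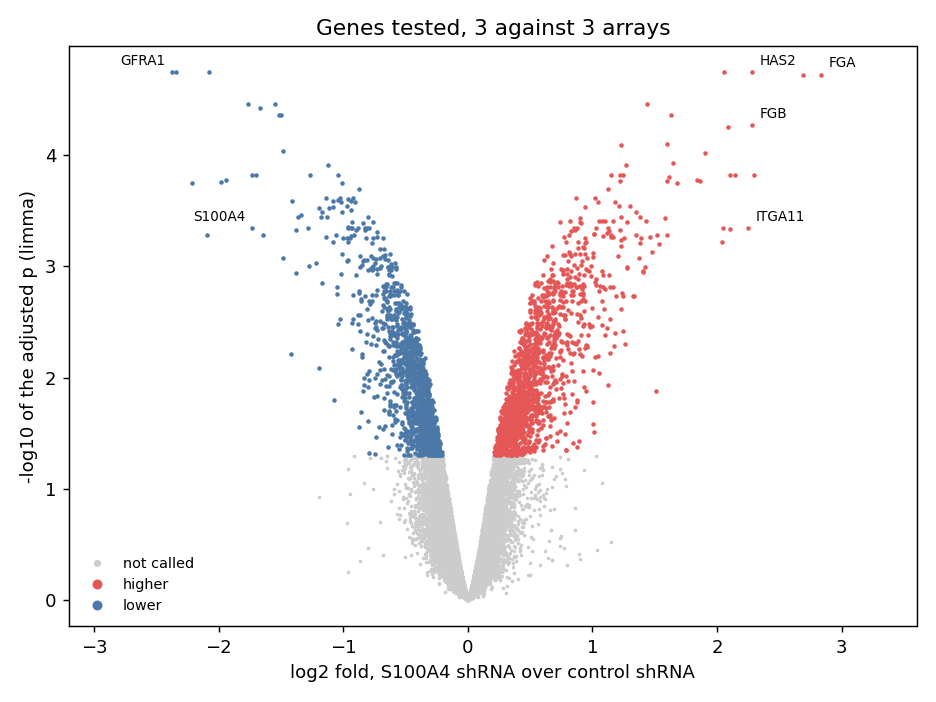
Log2 fold of each of the 25141 genes (S100A4 shRNA over control shRNA, horizontal axis) against -log10 of its limma adjusted p (vertical axis), with called genes in red (1529 higher) and blue (1381 lower). S100A4 at -1.73 lies among the largest falls, and FGA at 2.84 is the largest rise.

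Respiratory chain subunits were compared because the series asks about mitochondrial metabolism. Among complex I subunits, NDUFV2 rose by a log2 fold of 0.46, NDUFA2 by 0.46 and NDUFB5 by 0.32. The calls of NDUFA2 and NDUFB5 were each lost when any of 5 of the 6 arrays was left out (largest limma adjusted p 0.137 and 0.143). The mean log2 fold of the list was -0.0073 while its median was 0.013 and camera's direction was up (adjusted p = 0.398). In complexes II to V, 1 of 38 measured subunits was called: ATP5PB, a stalk subunit of ATP synthase, fell from 11.1 ± 0.07 to 9.98 ± 0.09 (SD, n = 3 each), a log2 fold of -1.13 (limma adjusted p = 0.000244), and it was the only member adjusted over the list alone. That list had a mean of -0.00075, a median of 0.030 and an upward camera direction (adjusted p = 0.538). WDR77, the measured protein-coding gene nearest to ATP5PB, also fell (log2 fold -0.58, limma adjusted p = 0.00216). It was the only one called of the 20 such genes nearest to ATP5PB. Whether these falls share a cause was not tested. Of 17 complex I assembly factors, NDUFAF7 fell (-0.29), a call lost when any of the 6 arrays was left out (limma adjusted p up to 0.102), and 16 were not called (1 adjusted over the list alone, camera adjusted p = 0.610).

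Genes of mitochondrial translation and upkeep were mostly not called. Of 77 subunits of the mitochondrial ribosome 8 fell, among them MRPS9 (-0.55), MRPS34 (-0.48), MRPS18B (-0.45) and MRPL35 (-0.40), 2 rose (MRPL42 and MRPL33) and 67 were not called (14 called adjusted over the list alone). The list's mean log2 fold was -0.088 (camera adjusted p = 0.0296, adjusted p = 0.79 with an estimated correlation, and limma's fry adjusted p = 0.194). Of 16 genes of mitochondrial biogenesis 4 fell and 12 were not called (7 called adjusted over the list alone): the mitochondrial transcription factors TFAM (-0.58) and TFB2M (-0.41), the helicase TWNK (-0.38) and the single-strand binding protein SSBP1 (-0.24). The mean was -0.16 (camera adjusted p = 0.0262, and adjusted p = 0.571 with an estimated correlation). In the authors' deposited table the log2 differences were smaller: -0.058 for TFAM, -0.056 for TFB2M, -0.21 for TWNK and -0.034 for SSBP1. Both list calls were lost in the authors' deposited table (means of -0.019 for the ribosome and -0.036 for biogenesis, camera on their p-values: adjusted p = 0.997 and 0.726) and without control replicate 1 (0.168 and 0.084) or S100A4 shRNA replicate 2 (0.301, at a mean of -0.051, and 0.0915); the ribosome's was also lost without control replicate 3 (0.0621). Array weights ended both calls too (0.0719 and 0.0686). The calls of SSBP1 (6 of the 6 arrays left out in turn), TWNK (5), TFAM (3), TFB2M (1) and MRPL35 (1) were also lost without 1 array, with limma adjusted p up to 0.109, 0.0904, 0.0645, 0.0569 and 0.0546. In the TCA cycle list IDH2 (0.96) and SUCLG2 (0.50) rose, PDHA1 (-0.40) fell and 19 of 22 members were not called (4 called adjusted over the list alone, mean 0.059, median -0.0021, camera adjusted p = 0.522, and 0.0416 on the authors' p-values); the call of PDHA1 was lost without control replicate 1, control replicate 3 or S100A4 shRNA replicate 1 (limma adjusted p up to 0.072). Among 24 glycolysis genes ALDOC (0.65), the glucose transporter SLC2A1 (0.57) and PDK1 (0.38) rose, LDHB fell (-0.25, a call lost when any of the 6 arrays was left out, limma adjusted p up to 0.0914) and 20 were not called (4 called adjusted over the list alone, camera adjusted p = 0.102, and 0.0242 without S100A4 shRNA replicate 2).

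Genes tied to invasion were compared next, and more of them rose than fell. Of 30 mesenchymal and EMT genes 10 rose, 1 fell and 19 were not called (14 called adjusted over the list alone). The fibronectin receptor chain ITGA5 rose by a log2 fold of 1.60, from 7.85 ± 0.21 to 9.45 ± 0.18 (SD, n = 3 each, limma adjusted p = 0.000523). The collagens COL1A1 and COL5A1 rose by 0.64 each, while the smooth muscle actin gene ACTA2 fell (-0.36). Vimentin (VIM) was not called, at a log2 fold of 0.030. The mean of the list was 0.29 and its median 0.087 (camera adjusted p = 0.00023, and adjusted p = 0.571 with an estimated correlation). The mean was 0.12 in the authors' deposited table and 0.48 without the lower 50% of genes by mean signal. Of 30 measured matrix proteolysis genes 12 rose, 0 fell and 18 were not called (13 called adjusted over the list alone), with MMP7 (0.94), ADAM12 (0.80) and RECK (0.76) as examples. RECK and TIMP1 (0.46) are inhibitors of proteases, and MMP7 and ADAM12 are proteases. The mean was 0.26 and the median 0.044 (camera adjusted p = 0.000406, and adjusted p = 0.571 with an estimated correlation). The mean was 0.43 without the lower 50% of genes, and in the authors' deposited table it was 0.11 and the call was lost (camera adjusted p = 0.118).

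Of 20 integrin chains 9 rose, among them ITGA11 (2.25), ITGA5 (1.60) and ITGA2 (0.94), 2 fell (ITGA4 at -0.58 and ITGA1 at -0.51) and 9 were not called (13 called adjusted over the list alone). The mean was 0.40 and the median 0.25 (camera adjusted p = 0.000406, and adjusted p = 0.571 with an estimated correlation), with a mean of 0.19 in the authors' deposited table and 0.96 without the lower 50% of genes by mean signal. Among 30 epithelial genes 4 rose and 4 fell: CLDN2 (1.23), E-cadherin (CDH1, 0.97) and JUP (0.92) were higher and the keratin KRT18 (-0.58) lower. That list had 22 members not called (8 called adjusted over the list alone), a mean of 0.059, a median of -0.023 and a camera adjusted p of 0.538. Of 18 other S100 genes S100A10 rose (0.47), a call lost when any of 4 of the 6 arrays was left out (limma adjusted p up to 0.0641), S100A3 fell (-0.48) and 16 were not called (2 called adjusted over the list alone, camera adjusted p = 0.610). S100A3 is the measured protein-coding gene nearest to the target S100A4, and the only one called of the 20 such genes nearest to it. Whether its fall comes with that position was not tested.

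**Figure D3:**
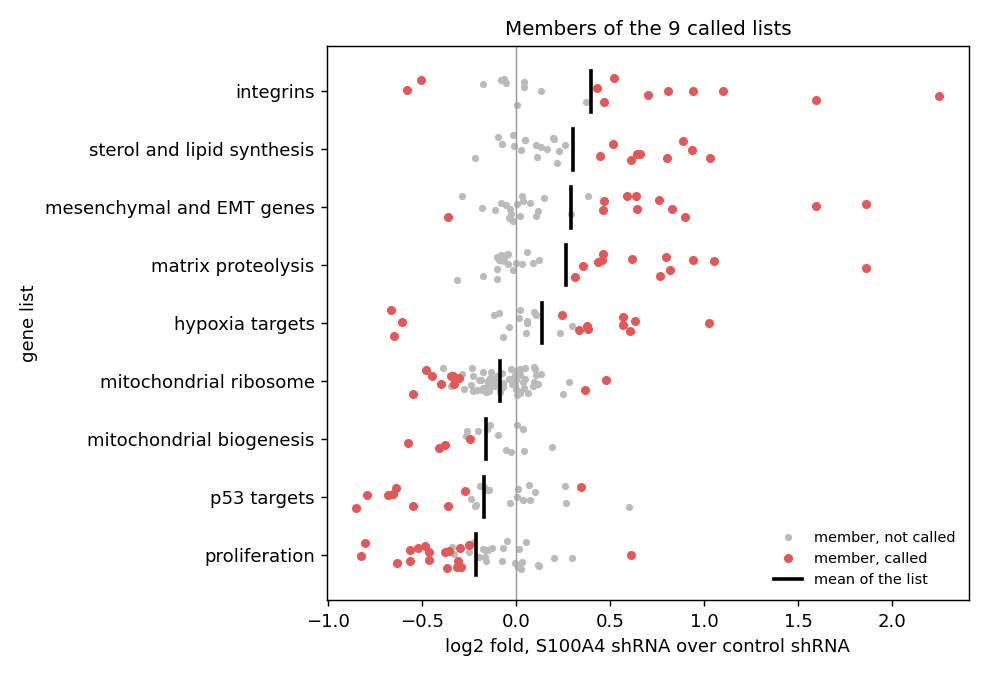
Log2 fold of each measured member (points, red where called by limma) and the mean of the list (black line) for the 9 lists called by camera. List means run from -0.21 for proliferation to 0.40 for integrins.

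Of 42 measured proliferation genes 17 fell, 1 rose and 24 were not called (22 called adjusted over the list alone). The replication helicase subunits MCM6 (-0.82), MCM4 (-0.81) and MCM2 (-0.57) fell, and cyclin E2, CCNE2, rose (0.61). The mean was -0.21 (camera adjusted p = 5.25e-05, and adjusted p = 0.571 with an estimated correlation), and in the authors' deposited table the mean was -0.044 and the call was lost (camera adjusted p = 0.705). Of 26 p53 targets 8 fell, among them PLK2 (-0.79), BTG2 (-0.68), MDM2 (-0.64) and SPATA18 (-0.55), CCNG1 rose (0.35) and 17 were not called (13 called adjusted over the list alone). The mean was -0.17 (camera adjusted p = 0.0361, and adjusted p = 0.79 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.118) or S100A4 shRNA replicate 2 (0.156), with array weights (0.0719) and by limma's fry (0.1001), and the mean was -0.11 in the authors' deposited table.

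Of 26 measured genes of sterol and lipid synthesis 9 rose, 0 fell and 17 were not called (14 called adjusted over the list alone), with STARD4 (1.03), the desaturase SCD (0.93), MSMO1 (0.89) and the squalene synthase FDFT1 (0.66) as examples. The mean was 0.30 (camera adjusted p = 5.51e-07, and adjusted p = 0.571 with an estimated correlation), and 0.17 in the authors' deposited table. Of 25 hypoxia targets 9 rose, among them the oxidoreductase ERO1A (1.02) and BNIP3L (0.63), 3 fell, among them ADM (-0.66) and EGLN1 (-0.65), and 13 were not called (13 called adjusted over the list alone). The mean was 0.14 (camera adjusted p = 0.00497, and adjusted p = 0.571 with an estimated correlation), and the call was lost when the lower 50% of genes by mean signal were left out (camera adjusted p = 0.0832). In the authors' deposited table the mean of the hypoxia list was 0.075.

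Other stress and signalling lists were not called by camera. Of 28 measured NRF2 targets 7 fell, among them GCLC (-0.88), GCLM (-0.87), HMOX1 (-0.83) and ME1 (-0.77), 4 rose and 17 were not called (16 called adjusted over the list alone, camera adjusted p = 0.151, and 0.0371 without control replicate 2). Of 28 ATF4 targets 7 rose, among them VLDLR (1.15), ALDH1L2 (0.44) and ASNS (0.42), 3 fell, among them the cystine transporter SLC7A11 (-0.92), and 18 were not called (14 called adjusted over the list alone, camera adjusted p = 0.0799, and 0.0309 without S100A4 shRNA replicate 2). Of 18 endoplasmic reticulum stress genes SEL1L (0.56) and XBP1 (0.55) rose, DNAJC3 fell (-0.26) and 15 were not called (5 called adjusted over the list alone, camera adjusted p = 0.151, 0.0272 without S100A4 shRNA replicate 2 and 0.0416 on the authors' p-values). DNAJC3 had the opposite sign in the authors' deposited table, a log2 difference of 0.069. Without 1 array, the calls of DNAJC3 (5 of the 6 arrays left out in turn), SAMD9L (3), ASNS (1) and IFI6 (1) were lost, with limma adjusted p up to 0.132, 0.0598, 0.0541 and 0.0541. Of 30 NF-kappaB and cytokine genes 6 rose, among them CCL2 (1.18), NFKBIZ (0.61) and CXCL1 (0.58), 3 fell, among them BIRC3 (-0.73), and 21 were not called (10 called adjusted over the list alone, mean 0.076, median -0.011, camera adjusted p = 0.522). Of 26 immediate early genes 4 rose (ZFP36 at 1.26, DUSP4 at 0.71, CCN2 at 0.38 and JUN at 0.34), 2 fell and 20 were not called (10 called adjusted over the list alone, mean 0.12, median -0.025, camera adjusted p = 0.352). Of 37 interferon-stimulated genes 4 rose (IFITM1 at 0.83, IFI6 at 0.83, OAS1 at 0.46 and SAMD9L at 0.36), 0 fell and 33 were not called (4 called adjusted over the list alone, mean 0.055, median -0.047, camera adjusted p = 0.398).

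Markers of lung and of other cell types were compared last. Among 14 alveolar type II markers CTSH (0.63) and ABCA3 (0.25) rose and 12 were not called (2 called adjusted over the list alone, mean 0.0060, median -0.066, camera direction down, adjusted p = 0.954). Among 15 fibroblast markers COL1A1 rose, FBN1 (-0.45) and THY1 (-0.31) fell and 12 were not called (3 called adjusted over the list alone, camera adjusted p = 0.410). Among 16 leukocyte markers CD68, a lysosomal protein also made outside leukocytes, rose (1.09), CD2 fell (-0.25) from a level of 3.84 below the negative control median, and 14 were not called (2 called adjusted over the list alone, camera adjusted p = 0.159, and 0.019 on the authors' p-values). Without 1 array, the calls of ABCA3 and CD2 (5 of the 6 arrays left out in turn) and THY1 (4) were lost, with limma adjusted p up to 0.132, 0.126 and 0.0741. The array's positive control probe sets are housekeeping controls, so they read RNA of the cells. They had a median of 13.5 ± 0.06 on the control arrays and 13.3 ± 0.13 on the S100A4 shRNA arrays (SD, n = 3 each). The difference of -0.23 (exact permutation p = 0.1, the smallest possible) goes with the same arrays as every gene group above. The means of the 4 lists that camera called downward lay between 0 and this difference. camera compared those lists with all other genes, not with these controls. Whether the difference of the controls comes from the cells or from the arrays was not tested.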

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

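The test of the mitochondrial clusters below the ceiling and the splits of the arrays were chosen after the results were seen. Transcript clusters without a gene name take no part in the comparisons of named genes, and among 40698 of them limma called 683 over all clusters (432 higher and 251 lower with S100A4 shRNA), 1.68% against 4.55% of named clusters. Among them are 22 clusters of the mitochondrial genome. Their identifiers carry the code of that chromosome, and for 18770 named clusters with an identifier of the usual form the code is the gene's chromosome in 99.957% of cases. Of these clusters 2 were higher in limma's test over all clusters, by log2 folds of 0.88 (SE 0.13, adjusted p = 0.0241) and 0.82 (SE 0.08, adjusted p = 0.00617).

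Transcript clusters of the mitochondrial genome were higher with S100A4 shRNA in the authors' deposited table, where 20 of 22 were higher and all 14 with an unadjusted p under 0.05 were higher. Among the 25141 named genes, 7392 had an unadjusted p under 0.05 in that table, in either direction. The median log2 difference of the mitochondrial clusters there was 0.16, outside the central 95% of 10000 sets matched on abundance (-0.047 to 0.047). Transcripts matched in this way did not share a shift of that size. The matched clusters were drawn independently, while clusters of 1 genome may move together, so this range does not measure chance. For the brightest clusters the nearest matches may be dimmer. In the values per array, 15 of them come within 0.5 of the ceiling of 19.93, which limits the rise they can show. The 7 below it had a mean log2 fold of 0.34 (95% interval over clusters 0.044 to 0.62, with overlapping probes possible between clusters). That interval treats the clusters as independent and does not measure the spread between arrays. Of these 7, 2 were called higher by limma, so for those 2 the rise was not limited to the workbook. A higher abundance of mitochondrial transcripts in the S100A4 shRNA cells stays open as a hypothesis, and a difference in RNA preparation between the groups was not tested.

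The split of the 6 arrays into the groups named by the labels gave 2910 genes by limma and the highest of the others gave 0, so 1 of 10 splits gave as many genes. With 10 splits a share under 0.05 cannot be reached. Each other split mixes both labels within its groups, so a difference between the labels adds to the spread there. The 0 genes of those splits thus do not show how many would be called without a difference.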

How the results depend on the processing

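Cyclic loess, the authors' workbook and the lists without shared members were chosen after seeing the data. S100A4 kept its direction and call in each alternative that tested it, with log2 folds of -1.82 to -1.59 without 1 array and -1.36 in the workbook. Leaving out 1 array gave 1539 to 2583 changed genes (762 to 1558 higher, 777 to 1025 lower) and 6 to 10 called lists. The count was 1146 (545 higher, 601 lower) with an ordinary linear model per gene after Benjamini-Hochberg, and 769 (471 and 298) at an unadjusted p under 0.05 with at least 1.5-fold. It was 1186 (638 and 548) at an adjusted p under 0.01, 760 (468 and 292) at an adjusted p under 0.05 with at least 1.5-fold, and 1903 over all transcript clusters (808 lower), where more features are tested. The authors' workbook gave 532 (262 and 270), for which the cause was not tested. With the replicate block 2883 genes were called, against 2910 without it, and the p53 target list was not (camera adjusted p = 0.0654). Samples with the same number correlated in their deviations at 0.084, 0.17 and -0.0087, and only number 2 correlated best with its own number. With so few arrays per group, these correlations cannot decide whether the numbers pair the samples. camera with an estimated correlation called 0 lists (0 at an unadjusted p under 0.05, 25 tested, 9 with the preset and 7 by fry), and there mesenchymal and EMT genes (0.29) and matrix proteolysis (0.26) lost their call; matrix proteolysis did so too in the workbook, at a mean log2 fold of 0.11. Without 1 array, the means of these lists were 0.25 to 0.32 and 0.25 to 0.29. The mean of complex I subunits, near 0 throughout and called in none of these, changed sign with array weights (0.018), in the workbook (0.0078) and without 1 array (-0.044 to 0.039). Other means near 0 that changed sign, none of them called in the main test, were leukocyte markers with quantile normalization (0.0013), without the lowest 25% of genes (0.016) and with cyclic loess (0.00078), the other S100 genes without the lower 50% (0.052), complexes II to V with array weights (0.027), in the workbook (0.0028) and without 1 array (-0.043 to 0.050), and alveolar type II markers in the workbook (-0.078) and without 1 array (-0.0065 to 0.020). In the workbook epithelial genes (-0.018), interferon-stimulated genes (-0.0022) and DNAJC3 (0.069) also changed sign; for all of these the cause was not tested. The call of the proliferation list was kept without each array, with a largest camera adjusted p of 0.00137, and after cyclic loess, where the mean was -0.20; in the workbook the mean was -0.044. Over all settings together, those above included, the 22 lists other than complex I, mesenchymal and EMT genes and matrix proteolysis kept sign and call in 349 cases, lost the call in 24, gained one in 7 and changed sign in 13, and single genes named by their size of change or their list kept both in 1549 and lost the call in 178. The planned use of values per array from the workbook was not run, since it holds group means. Signals near the negative controls, with a median of 4.18 to 4.27, limit what can be seen of dim genes. The ceiling of the value table limits what can be seen of the brightest.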

Other observations

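The genes named here were chosen after their values were seen, and the list of liver-type genes was written after the largest changes were seen. Of the 5 measured protein-coding interferon-induced transmembrane genes, 3 rose: IFITM2 by a log2 fold of 1.52 (SE 0.12), IFITM3 by 1.23 (SE 0.11) and IFITM1 by 0.83 (SE 0.09), with limma adjusted p-values of 0.000523, 0.000649 and 0.00166, while IFITM5 and IFITM10 were not called (-0.21 and -0.018, adjusted p = 0.162 and 0.904). No set test was made on this family, and the list of 37 interferon-stimulated genes was not called (camera adjusted p = 0.398). Several broadly expressed genes fell strongly: the phosphatase inhibitor ANP32A (-1.55), the transport protein TMED2 (-1.49), the ubiquitin-conjugating enzyme UBE2R2 (-1.41), the lipid hydroperoxide reductase GPX4 (-1.38), the proteasome subunit PSMA4 (-1.38) and the helicase DDX1 (-1.26), each with a limma adjusted p of 0.00114 or less.

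Besides FGA and FGB, other genes typical of hepatocytes rose, among them BAAT (1.35), APOH (1.27) and CP (1.23). A list of 56 further measured liver-type genes, written without any member already seen, was tested for the hypothesis that such genes rise as a class. It had 7 rises and 1 fall, a mean log2 fold of 0.019 and a camera p of 0.796, so this list did not rise against other genes. Members such as ALB (4.17), APOB (3.89) and SERPINA1 (3.72) read, with control shRNA, below the negative control median of any array. The list also left out the genes already seen to rise, so the test does not decide for the class. The 7 rises include SERPINA3 (0.91), FGL1 (0.66), HNF4A (0.57) and the fibrinogen gamma chain FGG (0.56).

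Fold changes of 10492 protein-coding genes with a mean signal above the median of all genes were set along the chromosomes in windows of 21 neighbours. The largest window median, 0.40 on chromosome 16 from RBL2 to MT1X, was reached in a share of 0.002 of 1000 shuffled gene orders. In the authors' workbook the chromosome 16 window stood 0.23 above the median of the 10492 genes (95% interval 0.053 to 0.36). The shift of that window was thus not limited to the value table. The interval treats the 21 genes as independent, and the workbook comes from the same arrays. The largest window of 1 other chromosome also exceeded the shuffled 95th percentile of 0.297, with a median of -0.35, but stood at -0.080 in the workbook (95% interval -0.16 to 0.12), so the summarisation stays open for it. Of 9 metallothionein genes in the chromosome 16 window 7 rose, among them MT1A (1.51) and MT2A (0.89), and the 12 others had a median of 0.14 (95% interval -0.19 to 0.60), so shared regulation of the metallothionein genes, or cross-hybridisation among them, may carry that window. Of these 12 other genes, 5 were called higher and 1 lower (RPGRIP1L, log2 fold -0.76). A copy-number difference between the lines stays open as a hypothesis.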
